A study of Arabidopsis thaliana with 119 samples.

How the data were processed

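RNA was measured in rosettes of 5 accessions of Arabidopsis thaliana under 4 treatments, in 119 libraries that form 20 groups of accession and treatment. Per the labels' protocols, total RNA was isolated with the RNeasy Plant Mini kit and libraries were made with the TruSeq Stranded mRNA kit. Per the submitters' processing notes, Trimmomatic 0.36 and HISAT2 were used. The counting tool, its strand setting and the genome build are not given in the sources used here. The authors deposited a table of whole-number counts per gene, with no normalization, for 32833 genes, of which 4657 had no count in any library. Every sample column matched a sample title. Reads of overlapping or antisense genes and of near-identical copies, such as the RBCS, LHCB and PDF1.2 families, LTP3 and LTP4, VSP1 and VSP2, CYP79F1 and CYP79F2, and MAM1 and MAM3, cannot be assigned with certainty, and their values are uncertain. All accessions were counted on the same gene models, which limits comparisons of level between accessions more than comparisons of treatments within an accession.

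Gene symbols came from the annotation of the TAIR10.1 assembly, used only for names, transcript length and GC content; 32548 of the gene IDs matched a locus tag. Transcript length was known for 19922 of the tested genes (99.5%). Total counts per library ranged from 9698710 to 110421000 and genes with a count from 19890 to 22964. Libraries of a group were compared before averaging, and in no group did a pair differ by as little as sampling noise, the lowest mean chi-square per gene being 3.07.

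The groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined, except the tests and alternatives named below as chosen later. Counts were normalized by TMM and filtered with filterByExpr, which left 20025 genes. All libraries entered a single quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3 with the group and the experiment code as terms, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Averaged contrasts weight the 5 accessions equally. Results were 3 averaged stress effects, non-additivity, 2 direct contrasts, 15 stress effects within accessions, 3 accession-by-stress interactions and the accession differences in the control condition. Log2 fold changes have the standard error of the fit, and CPM values are scaled by TMM library sizes. Principal components used log2 CPM with a prior count of 2.

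The 432 genes of 28 lists were written down from general knowledge, and 431 were in the table. Camera of limma 3.58.1 tested each list against other genes with a preset correlation of 0.01 and again with an estimated one, two-sided and adjusted over the lists. AOP2 was not analysed here. Median, mean and camera direction of a list differed in sign in some cases, as for heat shock genes in nitrogen deficiency (median 0.13, mean -0.09). Correlations between stresses were set beside 100 simulated sets of unchanged groups and beside controls split by replicate letter.

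Genes open to naming were set by a rule with 5 parts. For each averaged stress they were the 8 with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM and the same sign in all 5 accessions and within both codes. For non-additivity and the direct contrasts the same criteria gave 6 each way. For each list and comparison they were up to 4 members of lowest adjusted p, whichever way they went, which could also be named for single accessions. For each interaction they were the 8 of lowest p with a mean of at least 5 CPM. For accession differences they were the 10 of lowest p with that mean and all members of the natural variation list. Ties went by gene ID, and genes without a symbol are named by ID.

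The alternatives were RLE size factors, no filter, leaving out organelle genes, leaving out the code, each code alone, the replicate letter as a block, leaving out each letter, fitting an accession alone, limma voom, DESeq2 1.42.0 and, for lists and correlations, an estimated correlation and split controls. Leaving out the libraries far from their group, leaving out the Cvi-0 W+N- libraries highest in flower markers, a covariate for a length trend and, for genes called in both stresses, split controls were added after the data were seen. Chance was tested by relabelling treatments within accession and code, or accessions within code for the accession differences, and refitting with limma voom. For interactions the fitted accession and stress effects were kept, and what was left of each library was exchanged between the compared treatments. The fit was tested on simulated counts with 200 changed genes among 20025. For averaged drought it recovered 47 of 50 genes changed 1.5-fold, 48 of 50 at 2-fold and 49 of 50 at 4-fold. For drought in Col-0 it recovered 24, 42 and 49 of 50 at the same folds. At 1.25-fold it recovered 32 of 50 for averaged drought and 1 of 50 for drought in Col-0. Figures were drawn with matplotlib 3.10.9.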

Results

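Rosettes of Arabidopsis thaliana were profiled by RNA-seq in 5 natural accessions (Col-0, Bur-0, Cvi-0, Sha and Tsu-0) grown under 4 regimes of water and nitrate supply. Plants were grown in short days, spent 23 days on a Phenoscope, a robot that moves and waters each pot, and were sampled at 31 days. Control plants (W+N+) received 160.4 ± 7.96 ml of solution with 5 mM nitrate, and drought plants (W-N+) 50.9 ± 4.67 ml of the same strength. Nitrogen-deficient plants (W+N-) received 162 ± 11.1 ml with 0.5 mM nitrate, and plants under combined stress (W-N-) 50.7 ± 4.10 ml with 1.5 mM nitrate. Mean volume times concentration was 802 µmol of nitrate in the control, 254 µmol in drought, 81.0 µmol in nitrogen deficiency and 76.0 µmol in combined stress. The 20 groups held 6 libraries each, except Bur-0 W+N+ with 5. Total counts ran from 9698710 to 110421000 per library, with a median of 17998300. The labels do not say that replicates came from separate plants, so p-values measure the spread between these libraries.

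Accession was the main source of variation, with 62.9% of the sum of squares of log2 CPM, counts scaled by library size. Treatment held 10.6% and the accession-by-treatment term 4.08%. An experiment code in the sample titles, P3ID33 or P3ID34, whose meaning is not stated, held 2.68%, and 19.8% was left between libraries. Components 1 to 4 separated accessions, component 5 the treatments (R2 = 0.790), component 6 went with a trend on transcript length (R2 = 0.794, 4.65% of the variance) and component 7 with the codes (R2 = 0.578). Of the libraries, 4 stood far from their group: Tsu-0 W+N- d, Col-0 W+N+ f, Bur-0 W-N- c and Cvi-0 W+N+ c.

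**Figure D1:**
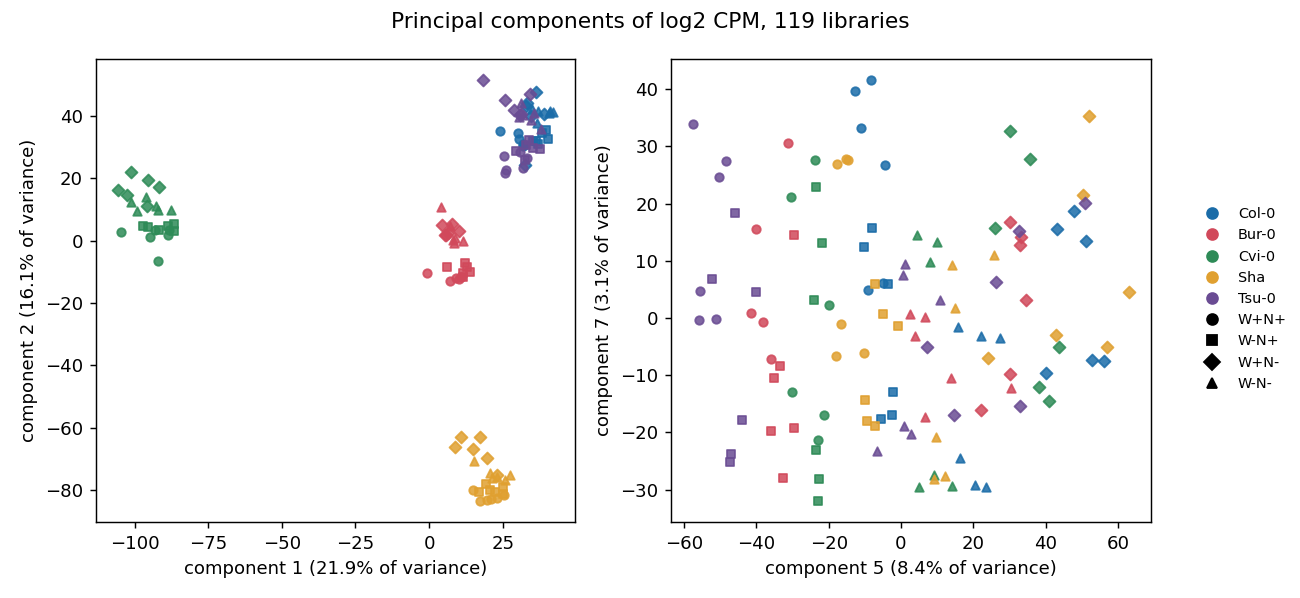
Principal components of log2 CPM, each point a library, with accession and treatment marked as in the legend. Components 1 and 2 (21.9% and 16.1% of the variance) separate accessions, and component 5 (8.37%) orders the treatments.

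Drought was set against control, averaged over accessions. Drought plants received less solution (50.9 ml against 160.4 ml). Effects of water, of nitrate and of anything else in the solution cannot be told apart in this contrast. RD20 (AT2G33380), a caleosin induced by dehydration and abscisic acid, was 2.31-fold higher (log2 1.21 ± 0.08 SE, edgeR adjusted p = 7.66e-23), at 70.8 ± 46.8 CPM (SD over accessions and replicates, n = 30) against 31.8 ± 25.9 CPM (n = 29). PAP17 (AT3G17790), a purple acid phosphatase of phosphate starvation, was 2.18-fold higher and PAP1 (AT1G56650) (MYB75), an activator of anthocyanin synthesis, 2.22-fold higher. The lipid transfer protein gene LTP4 (AT5G59310) was 2.39-fold higher and NUDT24 (AT5G19470), a nudix hydrolase homologue, 2.70-fold higher. The salicylic acid marker PR1 (AT2G14610) was 3.25-fold lower, the lipid-transfer-like gene EARLI1 (AT4G12480) 3.43-fold lower, the glucanase gene BG3 (AT3G57240) 2.77-fold lower and the early light-induced gene ELIP2 (AT4G14690) 2.45-fold lower. ORA59 (AT1G06160), a transcription factor of jasmonate and ethylene defence, was 2.42-fold lower. Each of these had the same sign in all 5 accessions and within both codes, which the rule for naming genes by the size of their change required.

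Among the gene lists, 21 of 37 abscisic acid and dehydration genes rose in drought (22 adjusted over the list alone). They included GOLS2, a galactinol synthase (log2 1.12 ± 0.11), and the bZIP factors ABF2 (0.39 ± 0.04) and ABF3 (0.45 ± 0.05). The proline catabolic gene PRODH1 fell (-1.03 ± 0.10) and the biosynthetic P5CS1 rose (0.81 ± 0.09), among 2 members higher and 2 lower of 7 (3 and 2 adjusted over the list alone). Of the phosphate starvation genes 10 of 15 rose (11 adjusted over the list alone), including SQD2 and SQD1 of sulfolipid synthesis (0.65 ± 0.04 and 0.44 ± 0.04) and SPX2 (0.41 ± 0.04). Anthocyanin and flavonoid genes rose in 12 of 27 cases (13 adjusted over the list alone), among them LDOX (1.01 ± 0.09) and DFR (1.08 ± 0.10). Aliphatic glucosinolate genes rose in 16 of 19 cases (16 adjusted over the list alone), by amounts such as 0.38 ± 0.06 for the regulator MYB29. Starch and sugar transport genes were higher in 4 of 8 cases (6 adjusted over the list alone), including the β-amylase BAM5 (1.09 ± 0.14) and the ADP-glucose pyrophosphorylase subunit APL4 (0.62 ± 0.08). Cytosolic ribosomal protein genes fell in 15 of 17 cases (17 adjusted over the list alone), as RPL4D did (-0.26 ± 0.05). Salicylic acid and defence genes fell in 9 of 16 cases (11 adjusted over the list alone), with PR5 2.01-fold lower. Nitrogen starvation genes fell in 9 of 17 cases (11 adjusted over the list alone), among them the transporters NRT2.1 (-0.95 ± 0.19) and NRT1.8 (-1.52 ± 0.29).

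The edgeR quasi-likelihood test called 4737 of 20025 genes (23.7%) in drought, 2120 higher and 2617 lower, of which 188 changed at least 2-fold. Within code P3ID33 alone 2318 genes were called, and within P3ID34 alone 2456. By camera the phosphate starvation, anthocyanin, aliphatic glucosinolate and nitrogen starvation lists passed with the preset correlation and with an estimated one (adjusted p = 0.000109, 0.0137, 0.0323 and 0.0443 with an estimated correlation). The abscisic acid, starch, ribosomal and defence lists passed with the preset only (adjusted p = 0.0502, 0.0502, 0.227 and 0.177 with an estimated correlation).

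Nitrogen deficiency against control changed more genes than either treatment with reduced water. GLN1;4 (AT5G16570), a cytosolic glutamine synthetase, rose 22.5-fold (log2 4.49 ± 0.12, edgeR adjusted p = 4.34e-59), from 7.76 ± 3.05 CPM (n = 29) to 177 ± 89.2 CPM (n = 30). The anthocyanin regulator PAP2 (AT1G66390) (MYB90) rose 25.9-fold, NUDT24 18.3-fold, the branched-chain aminotransferase gene BCAT-2 (AT1G10070) 14.0-fold and the nitrilase gene NIT4 (AT5G22300) by 3.33 ± 0.09 on the log2 scale. LBD39 (AT4G37540), a nitrate-induced repressor of anthocyanin synthesis, was 12.1-fold lower, PR1 7.99-fold lower and SRG3 (AT3G02040), a gene named for senescence, 8.26-fold lower. AT1G49500 was 39.2-fold lower, at 0.722 ± 0.583 CPM (n = 30) against 25.8 ± 14.3 CPM (n = 29).

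Nitrate assimilation and response genes fell in 15 of 20 cases (16 adjusted over the list alone), including the regulators HHO3 (-2.73 ± 0.10) and HHO2 (-1.80 ± 0.08) and the vacuolar nitrate exchanger CLCA (-2.17 ± 0.08). Nitrogen starvation genes rose in 13 of 17 cases (13 adjusted over the list alone), with the signal CEPDL2 at 4.65 ± 0.15, the nitrate transporter NRT2.5 at 4.59 ± 0.21 and the urea transporter DUR3 at 1.93 ± 0.08. Of the anthocyanin and flavonoid genes 26 of 27 rose (26 adjusted over the list alone), such as DFR (2.85 ± 0.10) and UF3GT (2.81 ± 0.09). Ammonium assimilation genes went both ways, 6 higher and 5 lower of 14 with the same counts adjusted over the list alone, the plastidic GLN2 at -0.56 ± 0.03 and the asparagine synthetase ASN2 at -1.58 ± 0.06. PRODH1 rose (1.94 ± 0.09) and P5CS1 fell (-1.43 ± 0.09), opposite to their signs in drought.

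Photosynthesis genes fell in 34 of 35 cases (34 adjusted over the list alone), with the Calvin cycle genes GAPA at -0.75 ± 0.04 and GAPB at -0.68 ± 0.04. All 17 ribosomal protein genes fell, with RPL5A at -0.92 ± 0.05. Cell division genes fell in 10 of 11 cases, including the cyclin gene CYCB1;2 (-0.57 ± 0.06), expansins in 5 of 6 and aquaporins in 14 of 16, including TIP2;1 (-1.17 ± 0.08). Cytokinin genes fell in 11 of 15 cases, with the synthesis gene IPT3 at -2.16 ± 0.10, and low-sugar genes in 7 of 9, with DIN10 at -2.22 ± 0.17. For these 6 lists the counts adjusted over the list alone were the same. Starch and sugar transport genes rose in 7 of 8 cases (7 adjusted over the list alone), including the starch synthase GBSS1 (1.75 ± 0.07) and the glucose 6-phosphate translocator GPT2 (2.67 ± 0.12). Senescence and autophagy genes rose in 12 of 21 cases and fell in 6 (12 and 6 adjusted over the list alone), with the chlorophyll breakdown genes PPH (2.14-fold) and NYE1 (1.22 ± 0.06) among those higher. Abscisic acid and dehydration genes were higher in 26 of 37 cases and lower in 7 (28 and 7 adjusted over the list alone).

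In nitrogen deficiency 13623 genes (68.0% of those tested) were called by edgeR, 7336 higher and 6287 lower, 1328 of them at least 2-fold. Counts of called list members are to be read beside that share. The P3ID33 libraries alone gave 11508 calls and those of P3ID34 11640. By camera the anthocyanin and nitrogen starvation lists passed with either correlation (adjusted p = 0.00468 and 0.0334 with an estimated correlation). The nitrate, starch, photosynthesis, ribosomal and cell division lists passed with the preset only (adjusted p = 0.107, 0.0575, 0.210, 0.202 and 0.459 with an estimated correlation). The same held for expansins, aquaporins, cytokinin, low-sugar, senescence and abscisic acid genes (adjusted p = 0.202, 0.210, 0.210, 0.210, 0.210 and 0.352 with an estimated correlation).

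**Figure D2:**
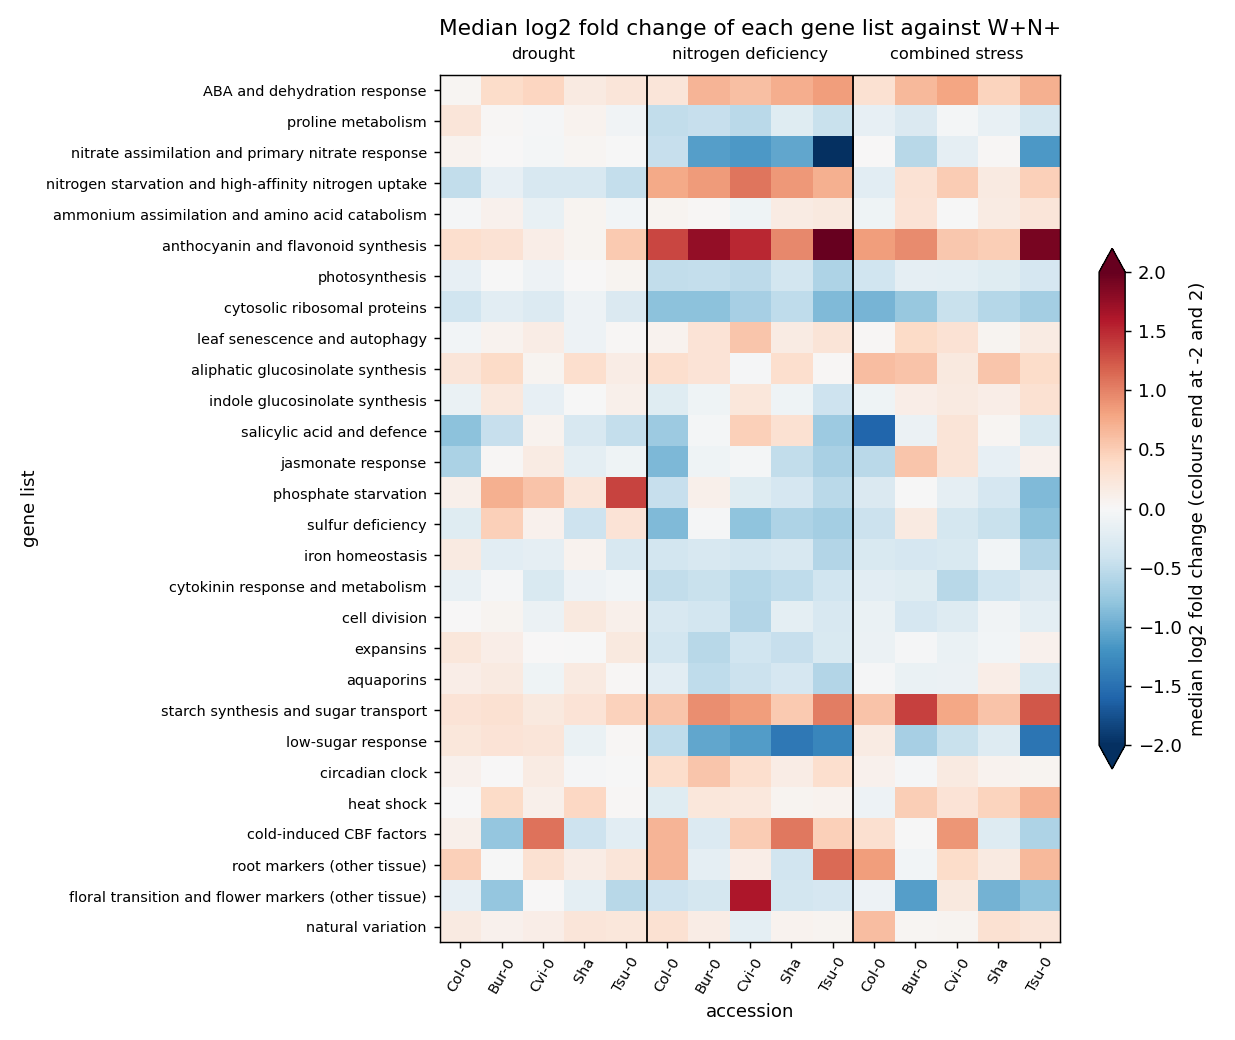
Median log2 fold change against W+N+ of each gene list (vertical axis) in each accession (horizontal axis) under the 3 stresses, with colour for the value as in the scale. The anthocyanin median in nitrogen deficiency is 2.48 in Tsu-0 and 0.97 in Sha, and the phosphate starvation median in drought is 1.34 in Tsu-0 and 0.10 in Col-0.

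Under combined stress anthocyanin synthesis genes were among the most increased. DFR (AT5G42800), a dihydroflavonol reductase, rose 5.56-fold (log2 2.48 ± 0.10, edgeR adjusted p = 3.19e-43), from 41.1 ± 44.7 CPM (n = 29) to 225 ± 214 CPM (n = 30), an SD that includes the differences between accessions. PAP1 rose 5.25-fold, the bHLH regulator TT8 (AT4G09820) 5.13-fold and NUDT24 15.6-fold. PR1 was 17.1-fold lower, ELIP2 5.71-fold lower and SRG3 6.80-fold lower. The defensin gene PDF1.2A (AT5G44420) was 4.14-fold lower, an uncertain value because its reads can be shared with near-identical copies.

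Of the abscisic acid and dehydration genes 32 of 37 rose under combined stress (32 adjusted over the list alone), with RD20 at 1.67 ± 0.09 and GOLS2 at 2.09 ± 0.11. Anthocyanin and flavonoid genes rose in 23 of 27 cases, aliphatic glucosinolate genes in 18 of 19 and starch and sugar transport genes in 7 of 8, with the same counts adjusted over the list alone. CYP79F1 and CYP79F2 of aliphatic glucosinolate synthesis, which are similar copies and so uncertain, stood at 0.62 ± 0.04 and 0.72 ± 0.04. All 17 ribosomal protein genes fell, as did 31 of 35 photosynthesis genes and 12 of 20 nitrate response genes, again with the same counts adjusted over the list alone. Phosphate starvation genes fell in 9 of 15 cases (9 adjusted over the list alone), with SPX1 at -0.88 ± 0.09 and PAP17 at -0.89 ± 0.08. Nitrogen starvation genes were higher in 8 of 17 cases and lower in 5 (9 and 6 adjusted over the list alone).

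Combined stress called 11468 genes (57.3%) in the edgeR test, 6133 higher and 5335 lower, 635 of them at least 2-fold. Code P3ID33 alone gave 9080 calls and P3ID34 alone 8874. The anthocyanin and starch lists passed camera with either correlation (adjusted p = 0.00306 and 0.00658 with an estimated correlation). The abscisic acid, aliphatic glucosinolate, ribosomal, photosynthesis, nitrate and phosphate lists passed with the preset only (adjusted p = 0.102, 0.0802, 0.110, 0.361, 0.358 and 0.358 with an estimated correlation).

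Combined stress was set directly against nitrogen deficiency, which had nearly the same total nitrate, more water and a lower nitrate concentration (0.5 mM against 1.5 mM). Effects of water, of concentration and of anything else in the solution cannot be told apart in this contrast. GLN1;4 was lower in combined stress (log2 -2.70 ± 0.11, edgeR adjusted p = 1.86e-42), at 31.9 ± 24.9 CPM against 177 ± 89.2 CPM (n = 30 each). PAP2 was lower (-2.59 ± 0.15) and AT1G49500 higher (2.71 ± 0.19). The lipid transfer genes LTP3 and LTP4, similar copies whose values are uncertain, were higher (2.66 ± 0.14 and 2.62 ± 0.22), as was the vegetative storage protein gene VSP1 (2.36 ± 0.27). Nitrogen starvation genes were lower in 13 of 17 cases (14 adjusted over the list alone), including CEPDL2 (-2.73 ± 0.12) and NRT2.5 (-2.67 ± 0.17). Nitrate response genes were higher in 15 of 20 cases (15 adjusted over the list alone), among them LBD37 (1.38 ± 0.11). Expansins were higher in 5 of 6 cases, aquaporins in 12 of 16, with PIP2;3 at 0.99 ± 0.06, and anthocyanin genes lower in 20 of 27 (5, 13 and 20 adjusted over the list alone). The contrast called 8168 genes (40.8%), 3932 higher and 4236 lower, against 4848 with P3ID33 alone and 6178 with P3ID34 alone. With an estimated correlation, camera adjusted p was 0.000227 for nitrogen starvation, 0.0247 for nitrate response, 0.0299 for expansins, 0.0619 for anthocyanin and 0.120 for aquaporin genes.

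Against drought alone, combined stress raised nitrogen starvation and anthocyanin genes and lowered phosphate starvation genes. SRG3 (-3.98 ± 0.12), PAP17 (-2.02 ± 0.08) and SPX1 (-1.67 ± 0.09) were lower, and BCAT-2 (2.26 ± 0.13) and GLN1;4 (2.26 ± 0.11) were higher. Phosphate starvation genes were lower in 11 of 15 cases, nitrogen starvation genes higher in 11 of 17 and anthocyanin genes higher in 23 of 27 (11, 11 and 23 adjusted over the list alone). These 3 lists passed camera with either correlation (adjusted p = 0.000661, 0.00474 and 0.00221 with an estimated correlation). The edgeR test called 9221 genes (46.0%), 5031 higher and 4190 lower, with 6759 for P3ID33 alone and 6074 for P3ID34 alone.

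Non-additivity was measured as the combined change minus the sum of the single-stress changes. Nitrate supply did not follow a full factorial. Drought alone cut it from 802 to 254 µmol, while combined stress (76.0 µmol) received nearly as much as nitrogen deficiency (81.0 µmol). The sum therefore counts a loss of nitrate in both single stresses. Non-additivity here is a departure from additivity of the treatments as applied. GLN1;4 (-2.23 ± 0.15), PAP2 (-2.29 ± 0.33) and NUDT24 (-1.66 ± 0.14) rose less in combined stress than the sum, and LBD39 (1.96 ± 0.18) and AT1G49500 (2.94 ± 0.23) fell less. The transporter family gene BOR5 was at -1.93 ± 0.16 and the cellulose synthase-like gene CSLA01 at 1.71 ± 0.34. Anthocyanin genes were below the sum in 21 of 27 cases and phosphate starvation genes in 10 of 15, and nitrate response genes above it in 13 of 20 (23, 10 and 13 adjusted over the list alone, camera adjusted p = 0.000475, 0.0108 and 0.0201 with an estimated correlation). By edgeR 6041 genes (30.2%) were non-additive, 3007 with P3ID33 alone and 3658 with P3ID34 alone. In 5926 of the 6041 (98.1%) the combined change was smaller than the sum. Over genes called in combined stress, a line through the origin fitted by total least squares, with error in both changes, had a slope of 0.621. Such a fit takes the errors of both as equal and independent. The sum and the combined change share controls, so the slope only describes these genes. Of the 1328 genes changed at least 2-fold in nitrogen deficiency, 1284 had the same sign under combined stress, with a median ratio of 0.594. The direct test called 965 of them smaller there and 27 larger, which choosing genes by their nitrogen change favours. When 1230 genes were chosen with P3ID33 and tested with P3ID34, 779 were smaller and 16 larger, and the other way round 821 and 32 of 1433. Of 635 genes chosen for a 2-fold change in combined stress, 231 were smaller there and 142 larger. All 3 stress changes share the control libraries, which by chance alone favours a combined change below the sum.

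**Figure D3:**
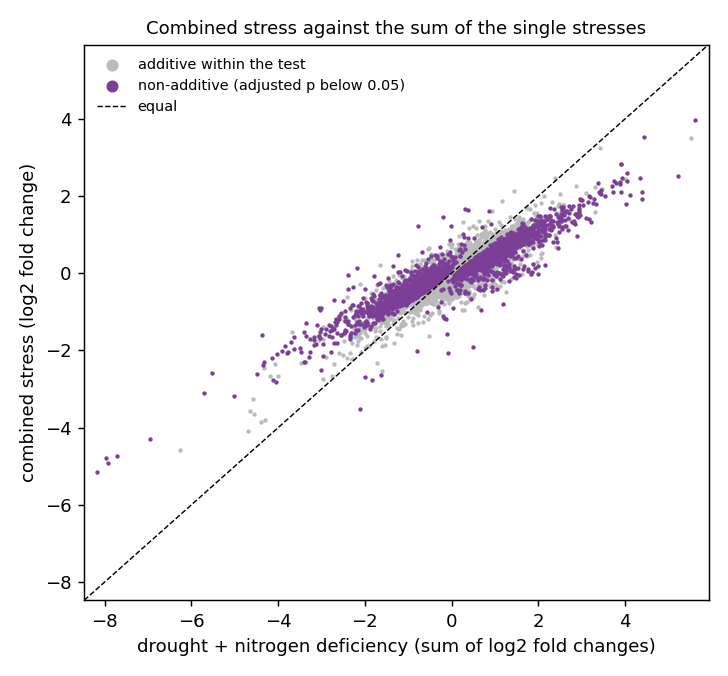
Combined-stress log2 fold change (vertical axis) against the sum of the drought and nitrogen deficiency log2 fold changes (horizontal axis), each point a gene averaged over accessions, with the 6041 non-additive genes coloured and a line of equality. In 98.1% of the coloured genes the combined change is smaller than the sum.

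Across genes, which are not independent replicates, the fold changes of nitrogen deficiency and combined stress correlated at 0.847, those of drought and combined stress at 0.676 and those of drought and nitrogen deficiency at 0.315. Simulated unchanged groups against the same controls gave 0.532, 0.485 and 0.519, and controls split between replicate letters 0.813, 0.601 and 0.270. The covariances were 0.176, 0.0581 and 0.0370 against simulated 0.00415, 0.00351 and 0.00408, so the differences were 0.172, 0.0546 and 0.0329. Drought and nitrogen deficiency shared 1412 genes higher and 1624 lower, where independent lists would share 777 and 822, and 845 genes were called in opposite directions against 1624 for independent lists. Nitrogen deficiency and combined stress shared 5252 higher and 4649 lower (2247 and 1675 for independent lists), and drought and combined stress 1777 and 1959 (649 and 697). Values for independent lists leave out the shared controls, which can raise such overlaps. Splitting the controls by letter also split them by code in Bur-0 and Tsu-0, where a to c were P3ID34 and d to f P3ID33. Each stress was then set against fewer control libraries. Lower values with split controls therefore cannot be put down to the shared controls alone. With the controls split by letter, so that the compared stresses had no library in common, drought and nitrogen deficiency shared 798 higher and 933 lower (426 and 442 for independent lists) with letters a to c for drought and 959 higher and 967 lower (524 and 481 for independent lists) with letters d to f. In opposite directions were then 477 (883) and 646 (1012). Nitrogen deficiency and combined stress shared 4299 higher and 3946 lower (1786 and 1311 for independent lists) and 4360 higher and 3920 lower (1760 and 1301 for independent lists), and drought and combined stress 1004 higher and 1140 lower (339.9 and 360.0 for independent lists) and 1201 higher and 1147 lower (412 and 389 for independent lists).

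Within single accessions, PR1 fell by 3.69 on the log2 scale in drought in Col-0 and stood at -0.48 in Sha. Defence genes fell in drought in 8 of 16 cases in Col-0, 3 in Bur-0, 3 in Tsu-0 (median -0.81, -0.46 and -0.48), while edgeR called none of them in Cvi-0 or Sha (median 0.08 and -0.31). The test of that difference called 0 of 16 (8 adjusted over the list alone). In combined stress 13 fell in Col-0, while 3 rose and 3 fell in Bur-0, 2 and 1 in Cvi-0, 1 and 2 in Sha, and 2 and 5 in Tsu-0. The accession-by-combined-stress test called 12 of 16 (14 adjusted over the list alone), against 13.5% of all genes. Anthocyanin genes rose in nitrogen deficiency in 26 of 27 cases in Tsu-0, 25 in Bur-0, 22 in Col-0, 22 in Cvi-0 and 19 in Sha. In drought edgeR called 1236 genes in Col-0, 1172 in Tsu-0, 654 in Bur-0, 344 in Sha and 325 in Cvi-0. Without the 4 libraries far from their groups these were 805, 1891, 991, 581 and 192. P3ID33 alone gave 1050, 626, 318, 84 and 20 drought calls in that order, and P3ID34 alone 178, 239, 127, 108 and 625. Nitrogen deficiency called 10180 genes in Tsu-0, 8512 in Cvi-0, 8506 in Col-0, 8303 in Bur-0 and 7670 in Sha, and combined stress 7518, 3939, 6240, 6451 and 3523 in that order.

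**Figure D4:**
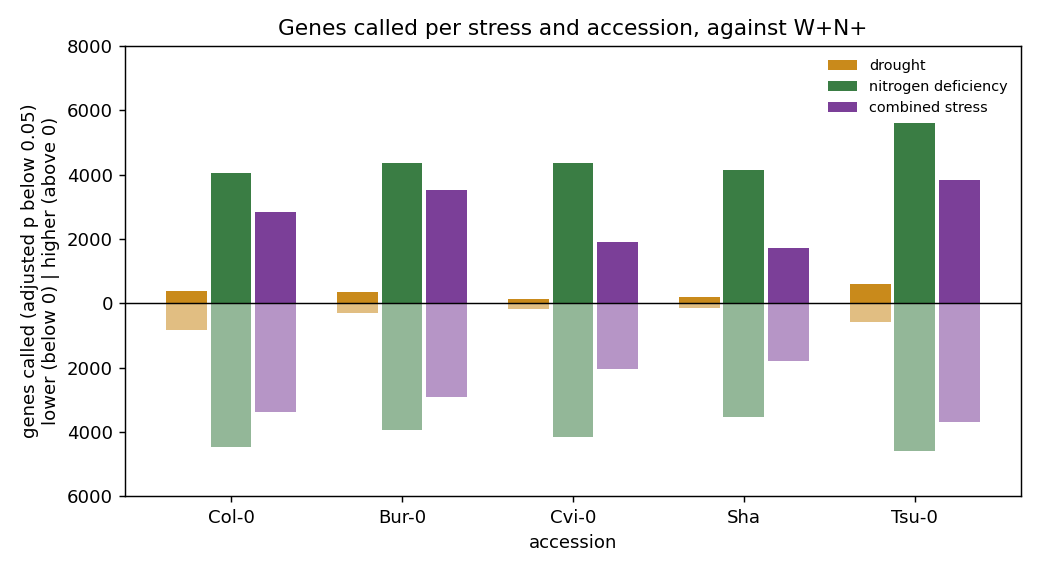
Number of genes called by edgeR against W+N+ in each accession under each stress, with higher and lower genes drawn apart. Nitrogen deficiency gives 7670 to 10180 calls per accession and drought 325 to 1236.

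The drought response differed between accessions in phosphate starvation genes. All drought plants received less solution, so a response to water cannot be told apart here from a response to anything else in the solution. SQD2 rose by 1.48 ± 0.08 in Tsu-0 and by 0.83 ± 0.08 in Bur-0 and stood at 0.18 ± 0.08 in Col-0 (edgeR interaction adjusted p = 1.57e-17). PS2, a pyrophosphatase gene, was at 2.14 in Tsu-0, 1.52 in Bur-0 and -1.47 in Col-0. The galactolipid synthase gene MGD3 was at 1.45 in Tsu-0 and -0.77 in Col-0, MGD2 was at -0.01 in Col-0 and went from 11.6 ± 1.85 to 30.7 ± 5.89 CPM in Tsu-0 (n = 6 each), and SRG3 was at 2.38 in Bur-0, 1.95 in Tsu-0 and -0.02 in Col-0. Of the phosphate starvation genes 11 of 15 were called in the accession-by-drought test (14 adjusted over the list alone), against 0.619% of all genes. In Tsu-0 14 of the 15 rose in drought, in Bur-0 9, in Cvi-0 8, in Sha 3 and in Col-0 1, with 3 lower in Col-0. The interaction test called 124 genes, 35 with P3ID33 alone and 30 with P3ID34 alone.

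Under nitrogen deficiency PAL2, a phenylalanine ammonia-lyase gene at the entry to phenylpropanoid synthesis, rose by 1.08 in Col-0 and from 108 ± 12.9 to 265 ± 87.7 CPM in Tsu-0 (n = 6 each), and stood at 0.15 in Bur-0, -0.10 in Cvi-0 and -0.33 in Sha. The iron superoxide dismutase gene FSD1 fell by 3.51 in Cvi-0 and went from 1272 ± 298 to 589.8 ± 118.6 CPM in Col-0 (n = 6 each), and CCS, a copper chaperone gene, rose by 2.36 in Bur-0 and 0.68 in Col-0. The transferase gene AT1G34060 was at 5.18 in Tsu-0 and 2.19 in Cvi-0. The accession-by-nitrogen test called 23 of 27 anthocyanin, 14 of 16 defence and 17 of 20 nitrate response genes (24, 15 and 17 adjusted over the list alone), against 16.1% of all genes. Defence genes rose in 8 of 16 cases in Cvi-0 and fell in 10 in Col-0 and 10 in Tsu-0. Floral transition and flower markers were higher in nitrogen deficiency in Cvi-0 in 3 of 5 cases (median 1.62), and the mean log2 CPM of all listed markers with a count was -0.23 ± 0.85 there against -1.37 ± 0.28 in the control (n = 6 each). Libraries e and f were the highest there, and without them nitrogen deficiency in Cvi-0 called 7207 genes and the accession-by-nitrogen test 2701. By edgeR 3229 genes were called with all libraries, 857 with P3ID33 alone and 1358 with P3ID34 alone.

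The combined stress response of GLN1;4 was 3.60 in Bur-0, 2.69 in Tsu-0 and 0.16 in Col-0. BGLU1, a glycosyl hydrolase gene, was at 0.21 in Cvi-0 and went from 51.6 ± 6.26 to 181 ± 32.8 CPM in Tsu-0 (n = 6 each), and PAL1 was at 1.52 in Tsu-0 and -0.02 in Sha. RSH3, a homologue of bacterial stringent-response enzymes, was at 1.41 in Tsu-0 and 0.39 in Sha. The oxygenase family gene AT2G25450 fell by 2.39 in Tsu-0 and was at 0.28 in Col-0. Anthocyanin genes were called in 19 of 27 cases and nitrogen starvation genes in 11 of 17 (22 and 13 adjusted over the list alone), against 13.5% of all genes. The edgeR test of the difference between accessions called 2712 genes, 2692 with P3ID33 alone and 922 with P3ID34 alone.

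**Figure D5:**
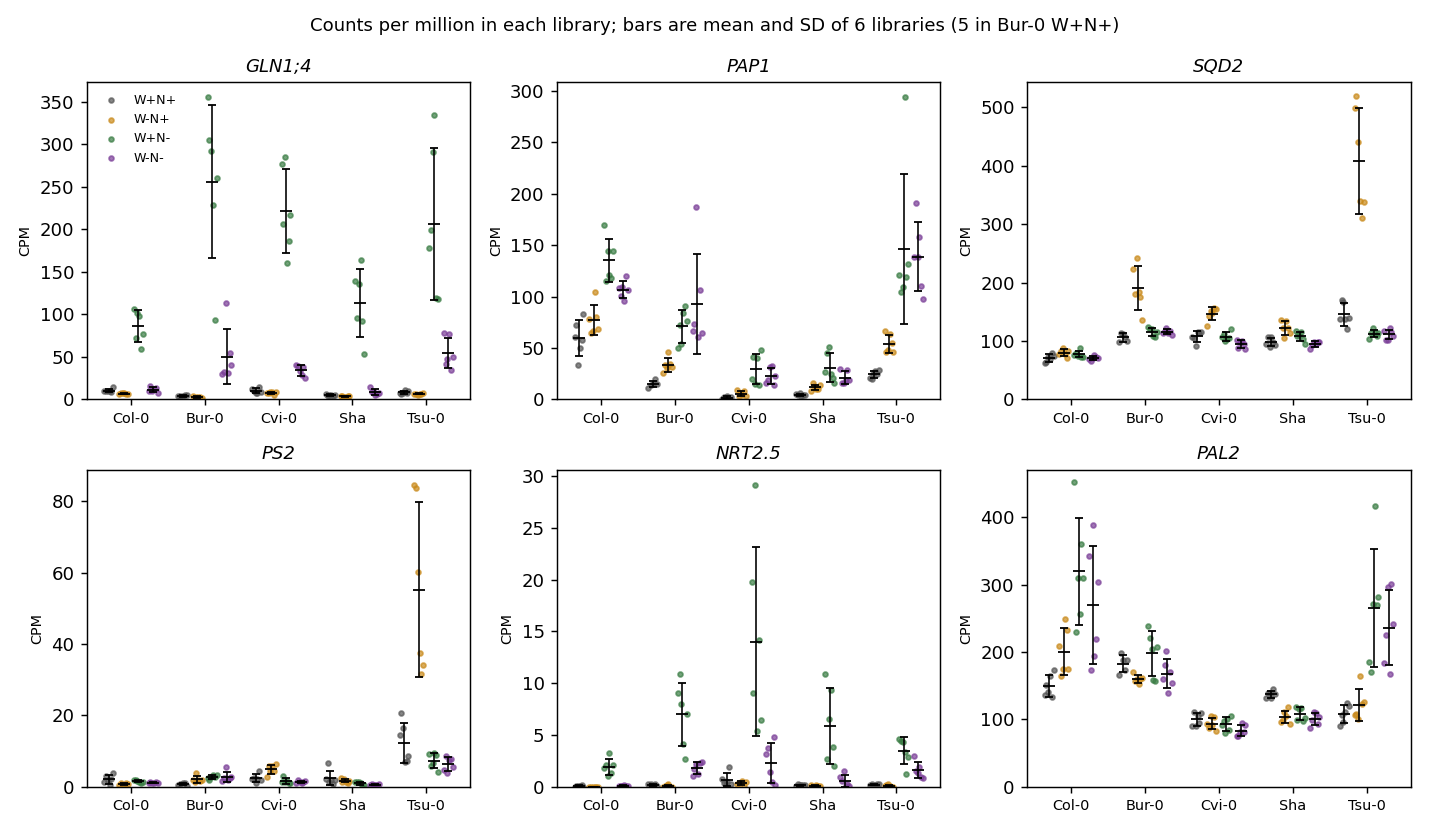
CPM of GLN1;4, PAP1, SQD2, PS2, NRT2.5 and PAL2 (vertical axes) by accession and treatment (horizontal axes and colours), with points for libraries and bars for mean and SD of 6 libraries, 5 in Bur-0 W+N+. GLN1;4 is at 206 ± 89.0 CPM in Tsu-0 W+N- and 8.35 ± 1.54 CPM in Tsu-0 W+N+, and SQD2 at 408 ± 90.3 CPM in Tsu-0 W-N+ and 146 ± 19.2 CPM in Tsu-0 W+N+.

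In the control condition AOP3, a dioxygenase gene of glucosinolate side-chain synthesis, was at 388 ± 19.5 CPM in Tsu-0 and at 0.0898 ± 0.0902 CPM in Cvi-0 (n = 6 each). HSD2, a hydroxysteroid dehydrogenase gene, was at 77.3 ± 15.6 CPM in Col-0, 82.0 ± 15.3 in Cvi-0 and 0.142 ± 0.134 in Sha. The phospholipase gene PLC8 was at 0.0453 ± 0.0557 CPM in Sha and 38.4 ± 2.48 CPM in Cvi-0, and the leucine-rich repeat gene AT4G16880 at 48.4 ± 5.14 CPM in Col-0 and 0.0603 ± 0.0620 CPM in Bur-0 (n = 5). The flowering repressor FLC was at 17.8 ± 4.87 CPM in Cvi-0 and 0.447 ± 0.266 CPM in Col-0, the epithiospecifier gene ESP at 47.3 ± 11.7 CPM in Col-0 and 3770 ± 374 CPM in Bur-0, and the dormancy gene DOG1 at 6.98 ± 1.23 CPM in Sha and 0.0719 ± 0.0594 CPM in Bur-0. All 10 tested genes of the natural variation list differed between accessions (10 adjusted over the list alone), as did 15138 genes (75.6%) by edgeR, 14040 within P3ID33 and 11431 within P3ID34. Counts rest on a single table of gene models, so a low count in an accession can also come from sequence that differs from the reference.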

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

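The tests of length, depth and tissue for the libraries far from their group, the relabelings between the compared treatments and the exchanges for interactions were chosen only after a first result was seen.

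Among 5 measures in 20 groups, 18 of 100 cases had a library set apart from its group by Dixon's test. Chance gives about 5 for normally distributed values. Whether these measures are so distributed was not tested, so no conclusion is drawn from the excess. Total counts (M) were 39.7 in Bur-0 W-N- b, 55.3 in Bur-0 W+N+ c, 43.9 in Cvi-0 W+N- f, 29.98 in Cvi-0 W+N+ c, 62.9 in Sha W+N- c, 110.4 in Tsu-0 W-N+ d and 27.1 in Tsu-0 W+N- e, each the highest of its group. The chloroplast share of counts was the highest of its group in Bur-0 W-N- d (0.0873%), Bur-0 W-N+ d (0.423%), Bur-0 W+N- d (0.248%), Col-0 W-N+ b (0.497%), Cvi-0 W+N+ d (0.687%), Sha W-N- a (0.125%), Sha W-N+ a (0.442%) and Sha W+N+ e (0.127%). The trend on transcript length was -0.32 log2 per doubling in Col-0 W+N- c, the lowest of its group. The mean log2 CPM of root markers was -1.28 in Sha W-N+ a, the lowest of its group, and -0.79 in Tsu-0 W-N+ c, the highest of its group.

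The stress response differed between accessions in 124 genes for drought, 3229 for nitrogen deficiency and 2712 for combined stress. For drought the adjusted p by edgeR was 1.57e-17 for SQD2, 3.85e-09 for PS2, 2.18e-08 for SRG3, 2.89e-06 for MGD2, 4.19e-06 for BGLU1, 4.19e-06 for MGD3, 6.26e-05 for GGCT2;1 and 0.000109 for the cytochrome P450 gene AT3G44970, which was at 1.32 in Cvi-0 and 0.04 in Col-0. For nitrogen deficiency it was 3.53e-15 for the amine oxidase gene AT3G43670, 5.225e-15 for AT2G29370, 5.225e-15 for AT1G34060, 5.225e-15 for PAL2, 1.26e-14 for BGLU1, 9.01e-14 for AT3G28270, 2.575e-13 for CCS and 8.315e-13 for FSD1. For combined stress it was 4.79e-16 for BGLU1, 4.79e-16 for AT1G34060, 1.90e-14 for AT2G25450, 6.76e-14 for PAL2, 1.95e-13 for GLN1;4, 1.55e-12 for PAL1, 2.60e-11 for RSH3 and 5.39e-11 for the racemase family gene AT1G15410. AT3G43670 was at 0.99 in Col-0 and -0.94 in Cvi-0, and AT3G28270 at 1.60 in Tsu-0 and -1.44 in Bur-0.

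The combined stress change was smaller than the sum of the single changes in 98.1% of non-additive genes. Chance in the shared control libraries was argued against, since of 3006 genes called with P3ID33 alone 98.5% had, in the separate P3ID34 libraries, a non-additivity opposite in sign to their sum of single changes with P3ID33. A trend with transcript length stays open. The share was at least 97.6% among short, middle and long transcripts, but it ignores the direction of change. A length trend in the shared control libraries would enter the sum through both single changes, so the share cannot decide. The nitrate concentration of the solution, 1.5 mM here and 0.5 mM in nitrogen deficiency, cannot be told apart from the added drought, because 0 other treatments received 1.5 mM. Total nitrate also fell in drought alone (254 µmol against 802 µmol in the control), so the sum counts a loss of nitrate in both single stresses. That can also place the combined change below the sum. A biological limit on joint responses stays open and was not tested.

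The libraries Tsu-0 W+N- d, Col-0 W+N+ f and Bur-0 W-N- c lay over 0.500 log2 units (root mean square) from their groups, the first pair at 0.751 and 0.712, against a median of 0.290 in the other libraries. Low depth was first tested by rank, where all 3 were among the shallowest libraries, as low depth predicted (percentiles 8.47, 5.93 and 7.63). That test was then replaced. The 8 other libraries of such depth lay only 0.291 to 0.376 from their groups, which argues against low depth as the whole cause. A smaller part played by depth was not tested. Transcript length or RNA integrity stays open: length explained 33.5%, 35.8% and 38.7% of their deviation, but up to 49.6% in another library. Root tissue was argued against, since 0 of the 3 had a root score above the mean of their group's other libraries and PYK10, abundant in roots and chosen after its values were seen, was at 14.2, 11.8 and 15.4 CPM against 23.7 ± 5.26, 16.7 ± 0.723 and 21.8 ± 5.11. Flower tissue stays open for Col-0 W+N+ f and Bur-0 W-N- c, 2 of the 3, whose flower marker scores, near the floor, were -1.73 and -1.38 against -1.84 ± 0.05 and -1.61 ± 0.06 (the score of Tsu-0 W+N- d was the lowest of its 6), and over the 5 markers tested in the fit Col-0 W+N+ f was instead the lowest of its group; no biological explanation was tested.

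The library Cvi-0 W+N+ c lay 0.715 log2 units from its group. Shoot apex tissue is a candidate explanation, as it was the highest of 6 for 11 of 14 apex markers (78.6%), such as LSH4 (60.8 CPM against 8.89 ± 6.01, n = 5) and CUC2 (1.90 against 0.255 ± 0.228), but not for ATH1, AIL6 or CLV3. The 15 markers were listed after other apex genes had been seen to be high in this library. A wrong label was argued against by a correlation of at most 0.154 of its deviation with the other Cvi-0 treatments, across genes. Low depth was argued against by its percentile of 89.8, and no biological explanation was tested.

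Treatments were relabelled 100 times, the real labels included, within accession and code, and counts were made by limma voom. For the accession differences, accessions were relabelled within code among the controls. Relabelings of treatments were first drawn across all 4 treatments and then, after those results were seen, between the compared treatments only, except for non-additivity. For averaged drought only 1 labelling, the real one, gave as many calls (4701 against at most 1), and chance was excluded there, as for nitrogen deficiency (13780 against 2453), combined stress (11622 against 1658), non-additivity (6103 against 1820), combined stress minus drought (9128 against 208) and minus nitrogen deficiency (8328 against 2654), and accession differences (15134 against 7207). Relabelling treatments removes the stress effect that an interaction is measured against, so those draws are not a fair test of interactions. Between the compared treatments 7 of 100 gave as many calls for the nitrogen interaction (highest 7759), which does not exclude chance, 3 for the combined stress interaction (highest 3286) and 1 for the drought interaction (highest other 84). Over all 4 treatments these were 1 (highest other 1957), 1 (13) and 3 (1446). The interactions were tested later by keeping the fitted accession and stress effects and exchanging what was left of each library between the compared treatments. By that test chance was excluded for the drought (111 against 2), nitrogen (3157 against 725) and combined stress interactions (2751 against 26), with 1 of 100, the real one, giving as many calls in each. Within accessions chance was excluded for drought in Col-0 (865 against 19) and Bur-0 (595 against 57). For drought in Sha chance was excluded between the compared treatments (292 against 2). Over all 4 it was not, since a relabelling there exceeded the real labels (1750 against 292). For drought in Cvi-0 2 of 100 gave as many calls, and a relabelling exceeded the real labels (829 against 698). The edgeR count there was 325, so chance was not excluded for it. For drought in Tsu-0 chance was excluded between the compared treatments (1163 against 268) but not over all 4, where 5 of 100 gave as many calls, the highest 4398. Over all 4 treatments 3 of 100 did for drought in Sha (highest 1750) and 2 of 100 for drought in Cvi-0 (highest 954).

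For nitrogen deficiency chance was excluded in Col-0 (8402 against 2976), Bur-0 (8461 against 5059), Cvi-0 (8839 against 5228), Sha (7754 against 4529) and Tsu-0 (10032 against 6666). For combined stress it was excluded in Col-0 (6189 against 2462), Bur-0 (6553 against 4323), Cvi-0 (4385 against 1881), Sha (3497 against 14) and Tsu-0 (7567 against 3915). Whether relabelings with very many calls carry part of the stress effects or another structure of the samples was not tested.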

How the results depend on the processing

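The alternatives without the 4 libraries far from their group, without the 2 Cvi-0 W+N- libraries highest in flower markers, with a length trend as a covariate and, for genes called in both stresses, with split controls were chosen after seeing the data. Results are counts of called genes, and the cause of a change was not tested unless named. RLE size factors, no filter, leaving out organelle genes and leaving out those Cvi-0 libraries left all 25 counts within 1.5 times, as did DESeq2 the 21 it was run for and leaving out any Bur-0 W+N+ library the 3 of Bur-0. Of 696 and 695 named-gene results 625 kept direction and call with P3ID33 alone and 638 with P3ID34 alone. All of these were called in the fit of all libraries. Genes named by the size of their change also had to have the same sign within both codes. This choice favours kept directions and calls in every alternative, so such counts are not an independent check. Replicate letters did not pair libraries: 21 of 87 same-letter pairs correlated above 0.1 (median 0.00324), in 0 of 15 comparisons all of them. With the replicate letter as a block all 25 counts stayed within 1.5 times, averaged drought at 4714, and 695 of 697 named-gene results kept direction and call. Each code alone holds fewer libraries. P3ID33 alone gave 2318 for averaged drought, 3007 for non-additivity, 4848 for combined stress minus nitrogen deficiency, 35 and 857 for the drought and nitrogen interactions, 318, 20, 84 and 626 for drought in Bur-0, Cvi-0, Sha and Tsu-0, 4038 and 6391 for nitrogen deficiency in Sha and Tsu-0, and 1302, 1447 and 4281 for combined stress in Cvi-0, Sha and Tsu-0. P3ID34 alone gave 2456 for averaged drought, 3658 for non-additivity, 6074 for combined stress minus drought, 30, 1358 and 922 for the 3 interactions, 178, 4284 and 2584 for the stresses in Col-0, 127, 4868 and 2495 in Bur-0, 108 and 1570 for drought and combined stress in Sha, 239 for drought in Tsu-0, and more, 625, for drought in Cvi-0, although the libraries were fewer. Without the code the drought and combined interactions had 62 and 1788, and drought in Col-0, Bur-0, Cvi-0, Sha and Tsu-0 715, 372, 139, 142 and 779. With the length trend, estimated from the residuals of the same data, so that its larger counts may be too high, the interactions had 2447, 8096 and 6517, drought in those accessions 4476, 1163, 2313, 717 and 2765, and combined stress in Cvi-0 and Sha 6188 and 5722. Without the 4 libraries drought had 805, 991, 192, 581 and 1891. Drought in Cvi-0 had 698 by limma voom and 172 when fitted alone. Leaving out a letter gave 56 to 90, 1955 to 3626 and 1612 to 2103 for the interactions and 414 to 1270, 348 to 838, 89 to 369, 121 to 414 and 509 to 1201 for drought in the accessions. With an estimated correlation the lists called by camera went from 10 to 4 in drought, 17 to 2 in nitrogen deficiency, 10 to 2 in combined stress, 14 to 4 for non-additivity, and 17 to 4 and 14 to 3 for combined stress minus drought and minus nitrogen deficiency. With split controls the correlations of the responses were 0.270, 0.601 and 0.813. A named-gene direction turned in 1 case, FT in combined stress with P3ID33 alone (0.0816 log2, edgeR adjusted p = 1). At this depth the simulated fit found 24 of 50 genes changed 1.5-fold in Col-0 drought, so many changes of that size were not detectable there; recovery within the other accessions was not measured.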

Other observations

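No test in this part was chosen after its result was seen, although which of the planned list results are described was. In nitrogen deficiency, sulfur deficiency genes fell in 10 of 12 cases (10 adjusted over the list alone), with SDI1, a repressor of glucosinolate synthesis, at -2.28 ± 0.15 and the sulfate reductase gene APR2 at -1.24 ± 0.10. Iron homeostasis genes fell in 8 of 11 cases (9 adjusted over the list alone), the peptide gene IMA3 at -3.74 ± 0.21, while the ferritin gene FER1 rose (1.39 ± 0.07). Jasmonate genes fell in 12 of 22 cases (12 adjusted over the list alone), including the synthesis genes AOS (-0.74 ± 0.08) and LOX2 (-0.79 ± 0.11), and LOX2 was higher in combined stress than in nitrogen deficiency (1.18 ± 0.11). By camera these lists had adjusted p = 0.00217, 0.0340 and 0.0340 with the preset, and adjusted p = 0.202, 0.202 and 0.506 with an estimated correlation. Indole glucosinolate genes went both ways, 2 higher and 4 lower of 8 with the same counts adjusted over the list alone. In nitrogen deficiency 68.0% of all tested genes were called. The regulator MYB51 was at 0.74 ± 0.11 and MYB34 at -0.49 ± 0.08. CYP81F2 fell in drought (-1.22 ± 0.16).

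Circadian clock genes were higher in 8 of 14 cases and lower in 3 in nitrogen deficiency (10 and 3 adjusted over the list alone, camera adjusted p = 0.123 with the preset), with ELF4 at 1.93 ± 0.13, FKF1 at 1.19 ± 0.10 and LHY at 0.64 ± 0.06; LHY fell in drought (-0.67 ± 0.06). Heat shock genes rose in 4 of 6 cases in combined stress (4 adjusted over the list alone, camera adjusted p = 0.156), and HSP70-4 also rose in nitrogen deficiency (0.82 ± 0.09). Of the cold-induced CBF factors CBF3 rose in nitrogen deficiency (1.12 ± 0.10), 1 of 3 of the list (1 adjusted over the list alone, camera adjusted p = 0.353). Root markers were higher in 2 of 4 cases in nitrogen deficiency (1 adjusted over the list alone, camera adjusted p = 0.392), of which FRO2 (1.56 ± 0.09) is also expressed in leaves. Apart from their rise in Cvi-0 in nitrogen deficiency, flower markers were lower in 3 of 5 cases in combined stress (3 adjusted over the list alone, camera adjusted p = 0.337), with AG at -0.93 ± 0.19 and the mobile flowering signal FT at -0.98 ± 0.41, a gene with a mean of only 0.106 CPM whose fall was not seen with P3ID33 alone.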
